A study of Mus musculus with 3 samples.

How the data were processed

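RNA of 3 cultures of wild-type mouse bone marrow derived dendritic cells was sequenced, 1 library each for untreated cells, cells treated with P. vulgatus and cells treated with YB328. Per the labels' protocols, total RNA was purified with the RNeasy Micro kit, cDNA was made with the SMART-Seq v4 Ultra Low Input kit and libraries were made with Nextera XT, a method that does not mark the strand. Per the submitters' processing notes, reads were processed with DRAGEN against the mouse genome GRCm38, without a version. The counting tool, the annotation release, the type of bone marrow culture, the dose, the exposure time and whether the bacteria were live are not given in the sources used here.

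The deposited table holds 55487 genes with Ensembl identifiers, positions and gene lengths, and, per the file headers, a TPM value and a count for each library. The deposited TPM values correct for gene length and sum to the same total in each library. The deposited count values are estimated counts (expected counts), not scaled between libraries. Values that are not whole made up 8.86%, 9.38% and 9.99% of genes in the untreated, P. vulgatus and YB328 libraries, and counts were rounded for intervals and thinning. Of the identifiers, 54435 were found in GENCODE M21, and all 54435 had the same coordinates there. A symbol was shared by several genes of the table in 234 cases.

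Counts were scaled between the 3 libraries by trimmed mean of M values (TMM) with edgeR 4.0.16 in R 4.3.3, used for size factors only, and all else was computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. With 1 library per group no test across libraries was possible and no p-value is given. A gene counted as higher or lower by a fixed rule of size: at least 5 CPM in at least 1 library, a log2 ratio of at least 1 in size after adding 0.5 CPM, and an exact 95% Clopper-Pearson interval of the count ratio, conditional on the sum, that excludes 1. The intervals cover counting error only. Folds are ratios of CPM without the added 0.5, and a gene with 0 counts in a library is given as at least the fold reached from a floor of 3 counts, which is 0.194 CPM in the untreated library, 0.114 CPM with P. vulgatus and 0.110 CPM with YB328. The comparisons were YB328 with untreated, P. vulgatus with untreated, and YB328 with P. vulgatus.

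Fixed lists of genes, 25 of functions and 13 of cell type markers, were written before the data were examined, as were the rule of size, the rule for named genes and all alternatives but 1. Members with at least 5 CPM in a library counted as expressed, and lists with at least 5 such members were placed by their median log2 ratio among 10000 random lists of the same size, drawn within 20 bins of mean expression (seed 1). A list stood apart at or below percentile 2.5 or at or above percentile 97.5. The text names, per comparison, the 12 highest and 10 lowest genes among those that passed with at least 20 CPM in the higher library, without predicted or clone-named models and receptor segments, up to 4 members per list with the largest ratios, and a fixed panel of 27 genes. Setting members with 0 counts to their bound shifted list medians by 0. The overlap of the responses was set beside the overlap of independent lists and beside 20 simulations of unchanged groups that share the untreated library.

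The method was tested on simulated data, with 200 changed genes and 10499 unchanged genes. With counting noise alone 0 unchanged genes passed, and 100% of genes changed 4-fold and 8-fold were recovered. Genes changed 2-fold, at the limit of the rule, were recovered in 40.3%, 35.8% and 31.3% of cases for YB328 with untreated, P. vulgatus with untreated and YB328 with P. vulgatus. With a spread between libraries of 0.2 (coefficient of variation) 192, 200 and 171 unchanged genes passed in the same order, and with 0.4 there were 2218, 2231 and 2216. A shifted list lay at percentile 100, and 2, 3 and 2 of 34 other lists stood apart.

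The alternatives were total count scaling, median-of-ratios size factors, TMM without the 10 most abundant genes of each library, the deposited TPM, no minimum CPM, a minimum of 20 CPM, 0.1 or 2 CPM added, thinning to the shallowest library, and the mean of list members in place of the median. Scaling and comparing nuclear protein-coding genes without Lars2 was chosen after seeing the data. Trends of the log2 ratio with gene length, GC content and mean expression were fitted by least squares with squared terms, where straight lines had been written down, and the fits with straight lines or without expression were added after seeing the data. Reads, splicing, transcripts and genetic variants were not analysed here, and the result of 1 gene is not reported here.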

Results

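Gene expression was measured by RNA sequencing in mouse bone marrow derived dendritic cells (BMDCs), antigen-presenting cells grown from marrow progenitors. The cells were wild type and came in 3 cultures: untreated, treated with P. vulgatus (Phocaeicola vulgatus, a common gut bacterium), and treated with YB328 (a gut bacterial strain). Each culture gave 1 library, so no difference below has a replicate check, and each comparison sets 1 library against another. The series concerns how gut bacteria improve the response of tumours to antibodies against PD-1, and the comparisons ask how dendritic cells differ after contact with each bacterium. The deposited gene counts summed to 15538133 in the untreated library, 26660869.8 in the P. vulgatus library and 26924006 in the YB328 library. A gene count of at least 1 was found for 19222, 19439 and 19503 genes in that order. Levels are given in CPM, counts scaled to a common library size. "Rose" and "fell" are used only for genes with at least 5 CPM in a library, a ratio of at least 2 after adding 0.5 CPM, and a 95% interval of the ratio that excludes 1. The intervals and floors cover counting error only. Amplified reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

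The untreated library differed from both bacterial libraries in the kinds of RNA it held. Ribosomal RNA genes took 9.54% of its counts, against 0.789% with P. vulgatus and 0.386% with YB328. Mitochondrial protein-coding genes took 12.8%, 0.748% and 0.577% in the same order, and mitochondrial ribosomal RNA took 4.51%, 0.498% and 0.321%. Malat1, a long noncoding RNA kept in the nucleus and chosen after its values were seen, took 1.0003%, 0.141% and 0.0930%. Lars2, a nuclear gene for a mitochondrial tRNA synthetase, took 6.72%, 0.309% and 0.157%. Nuclear protein-coding genes other than Lars2 took 57.9% of counts in the untreated library, 95.3% with P. vulgatus and 96.6% with YB328. This difference in RNA makeup stands beside every comparison with the untreated library below.

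**Figure D1:**
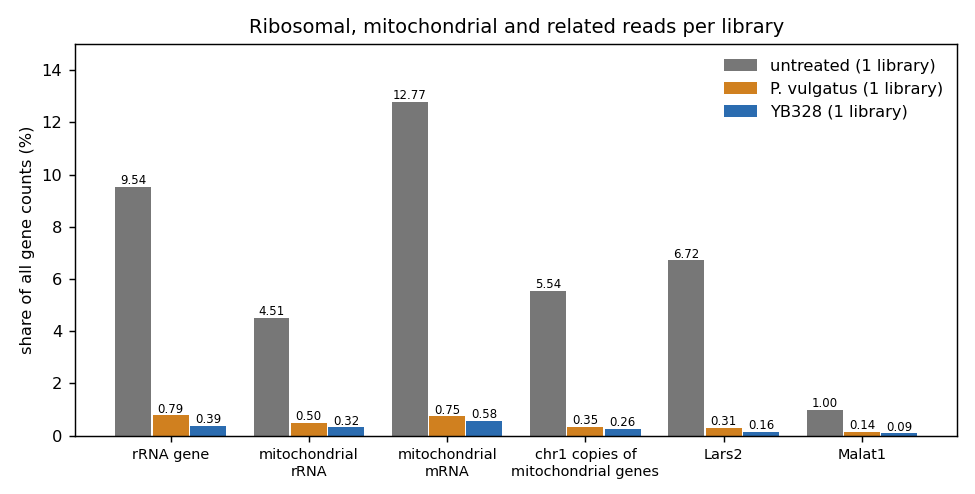
Share of all gene counts (%, y axis) taken by ribosomal, mitochondrial and related genes in the untreated, P. vulgatus and YB328 libraries (1 library each). Mitochondrial protein-coding genes took 12.8% in the untreated library and 0.577% in the YB328 library.

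The comparison of YB328 with untreated cells asks how BMDCs respond to this strain. Most genes of the lists for interferon response, cytokines, chemokines, class I presentation and costimulation rose in the YB328 library, and most cell cycle, neutrophil and ribosomal protein genes fell. Nos2 (ENSMUSG00000020826.9, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, rose from 0.323 to 1239 CPM, a ratio of 3839 (95% interval 1645 to 11824) that rests on 5 counts in the untreated library. The interferon-induced genes Irf7 (ENSMUSG00000025498.15, chromosome 7, 141262706 to 141266481) and Isg15 (ENSMUSG00000035692.7, chromosome 4, 156199455 to 156200796) rose 249-fold (95% interval 205 to 305) and 169.6-fold (95% interval 137 to 213). The collagen gene Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) fell from 204 to 2.27 CPM. In all, 2647 genes rose and 1955 fell among the 10699 genes with at least 5 CPM in a library, and 1000 and 725 of these did so by at least 2 on the log2 scale.

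Type I interferon response genes were the most uniformly higher group: 42 of 43 expressed members rose and 0 fell. The median log2 ratio was 4.34, at percentile 100 among 10000 random lists of the same size matched on expression, a percentile given throughout as a description of these libraries. Cmpk2 rose 297-fold, Oasl1 rose 236-fold, Rsad2 (viperin) rose 176-fold (95% interval 153 to 203) and Ly6a rose 354-fold. Of 25 guanylate-binding protein, immunity-related GTPase and other interferon gamma response genes, 20 rose and 0 fell (median log2 ratio 2.77, percentile 100). Gbp6 rose from 0.382 to 170.3 CPM, Igtp rose from 4.84 to 143 CPM, and the chemokine Cxcl10 rose 29.5-fold. The family members Gbp6, Ifi206 (which rose from 0.415 to 147 CPM) and Ly6a have close relatives, and the split of reads among relatives is uncertain. Ifnb1, the interferon beta gene, had 0 counts in the untreated library and 32 with YB328, at least 6.06-fold higher against a floor of 3 counts, but at 1.17 CPM it lay below the level needed to pass.

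Genes of dendritic cell maturation were also higher. Of 19 costimulation and maturation genes, 15 rose and 1 fell (median log2 ratio 1.71, percentile 99.9). Cd40 rose 7.75-fold (95% interval 7.17 to 8.39), Cd86 rose 5.91-fold, Cd83 rose 3.23-fold and Cd80 rose 2.07-fold, while Slamf1 and Tnfsf4 rose 28.6-fold and 11.9-fold. Cd80 did not pass when only nuclear protein-coding genes were scaled and compared, an alternative chosen after seeing the data, with a log2 ratio of 0.89. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose from 672 to 4679 CPM. Of 23 genes of class I presentation, 20 rose and 0 fell (median log2 ratio 1.78, percentile 99.96), including H2-K1, which rose 5.76-fold, Tapbp (8.09-fold) and H2-T22 (18.4-fold, a member of a family of near-identical genes). The 13 genes of class II presentation had median log2 ratio -0.02, percentile 3.44, with 2 higher and 2 lower. H2-Ab1 stood at 2222 CPM untreated and 2185 CPM with YB328, Lgmn and Ctss rose, and the peptide-loading genes H2-DMa and H2-DMb1 fell 4.59-fold and 2.40-fold.

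Among 20 cytokine genes, 16 rose and 1 fell (median log2 ratio 2.25, percentile 100). Il6 rose 56.3-fold (95% interval 45.8 to 70.1), Il1a rose from 6.84 to 679 CPM and Il12b rose 6.52-fold. Il12a had 1 count untreated and 217 with YB328, a ratio of 123 (95% interval 21.9 to 4895), below the minimum where 20 CPM was asked, and Csf3 had 1 count and 1174, a ratio of 668 (95% interval 119.6 to 26387). Il10 had 0 counts untreated and 29.2 CPM with YB328, at least 151-fold higher. Tnf did not pass, at 64.9 and 81.1 CPM. Among 18 chemokine genes, 12 rose and 2 fell (median log2 ratio 2.33, percentile 100), with Cxcl3 from 14.4 to 1882 CPM and Cxcl5 from 3.74 to 151 CPM. Cxcl1 rose from 3 counts to 6101, a ratio of 1156 (95% interval 395 to 5608). Cxcl9 was low, with 0 counts untreated and 1.54 CPM with YB328. Among genes for regulatory ligands and enzymes, 13 of 17 rose and 0 fell (median log2 ratio 2.71, percentile 100). They included Cd274, which encodes PD-L1 and rose 6.83-fold (95% interval 6.54 to 7.14), Cd200, which rose 16.0-fold, and Havcr2, which rose from 0.387 to 22.9 CPM.

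Further lists of signalling, metabolism and the lysosome stood apart on the higher side. Of 35 NF-kB targets and feedback genes 20 rose and 0 fell (median log2 ratio 1.36, percentile 99.97), with the acute phase gene Saa3 up 68.5-fold and Sod2 up 8.03-fold. Of 25 Toll-like receptor signalling genes 15 rose and 2 fell (median log2 ratio 1.32, percentile 99.95). Among the receptors themselves Tlr1 rose from 0.323 to 25.5 CPM, Tlr2 rose 2.26-fold, Tlr4 rose 4.48-fold, Tlr3 rose 5.27-fold and Tlr7 rose 4.09-fold, while Tlr11 fell from 6.71 to 0.183 CPM. Tlr3 stayed below the minimum, and so did not pass, with TPM or with at least 20 CPM. Tlr9 stood at 0.258 and 1.80 CPM and Tlr5 at 0.0645 and 0.807 CPM, both too low to pass. Of 24 oxidative stress genes under NRF2 18 rose and 0 fell (median log2 ratio 1.67, percentile 99.95), led by Hmox1 (29.0-fold) and Sqstm1 (7.69-fold). Of 33 lysosomal genes 22 rose (median log2 ratio 1.51, percentile 100), including Gpnmb (20.6-fold) and the protease gene Ctsl (11.2-fold). Of 32 glycolysis and hypoxia genes 20 rose and 0 fell (median log2 ratio 1.47, percentile 99.98), among them the lactate transporter gene Slc16a3 (10.1-fold). Of 18 immunometabolic enzyme genes 9 rose and 2 fell (median log2 ratio 1.13, percentile 98.4), and the prostaglandin synthesis genes Ptgs2 and Ptges rose 314-fold and 244-fold.

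Several groups were lower with YB328. Of 33 cell cycle genes 0 rose and 24 fell (median log2 ratio -2.14, percentile 0), with Top2a, the DNA topoisomerase of dividing cells, down from 77.1 to 2.61 CPM, Birc5 down 46.4-fold and Ube2c down 64.4-fold. Clspn, a replication checkpoint gene, fell from 319 counts to 1, a ratio of untreated to YB328 of 561 (95% interval 99.98 to 22229). Of 14 neutrophil markers 12 fell and 1 rose (median log2 ratio -2.29, percentile 0). S100a9 fell from 1865 to 90.7 CPM, S100a8 fell from 1853 to 139 CPM, Ngp fell 12.2-fold and Camp fell 15.9-fold. Of 44 genes for cytosolic ribosomal proteins 25 fell and 0 rose (median log2 ratio -1.06, percentile 0), for example Rpl12 (6.06-fold) and Rplp2 (5.05-fold). All 13 mitochondrially encoded genes fell (median log2 ratio -4.62, percentile 0), with mt-Cytb down 28.0-fold, alongside the larger mitochondrial share of the untreated library given above. Lars2 fell 43.5-fold (95% interval 43.0 to 43.9), beside ribosomal RNA gene shares of 9.54% untreated and 0.386% with YB328. Reads were not analysed, so whether the Lars2 counts come from its own transcript was not tested. The overlapping transcripts Tsix and Xist were read from 285 and 293 CPM down to 5.73 and 35.5 CPM. The library kit does not mark strand, so reads of Tsix and Xist are not separable. The 38 nuclear genes of oxidative phosphorylation had a median of 0.05, at percentile 0.680 and so below matched lists, and the median turned to -0.10 when nuclear protein-coding genes alone were scaled and compared. Among the 38, 1 rose (Ndufa9, 2.83-fold) and 4 fell, Ndufa5, Cox5a and Ndufa4 among them. The collagen genes Col1a2 and Col6a2 fell 61.7-fold (95% interval 51.6 to 74.3) and 148-fold (95% interval 67.7 to 406). Asgr2, a lectin gene, fell 108-fold, Clec4b1, another lectin gene, fell 106-fold, and Sap25 fell 52.2-fold.

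Marker lists of cell types did not move as blocks except for neutrophils. Of 11 markers of conventional dendritic cells of type 1, 3 rose and 3 fell (median log2 ratio 0.60, percentile 66.8). Irf8 rose 5.90-fold, Naaa fell 5.39-fold and Wdfy4 fell 6.37-fold. Batf3 stood at 109 and 119.9 CPM. Xcr1 and Itgae were low in both libraries, at 0.258 and 2.24 CPM and at 0.774 and 1.10 CPM, and Clec9a had 1 count untreated and 0 with YB328. Of 12 type 2 markers 2 rose and 5 fell (median log2 ratio 0.13, percentile 33.2), with Mgl2 down from 495 to 36.2 CPM and Ltb down 25.4-fold. The mean of the type 2 members turned to -0.82. Of 16 macrophage markers 7 rose and 1 fell (median log2 ratio 0.50, percentile 56.6), with Ms4a7 up from 0.645 to 114 CPM and Mrc1 down 12.9-fold. Of 14 monocyte markers 5 rose and 4 fell (median log2 ratio 0.10, percentile 37.3), with Ccr2 down 34.2-fold and Thbs1 up 12.7-fold. The lists for plasmacytoid dendritic cells (median log2 ratio 0.10, percentile 62.3), mast cells with basophils and eosinophils (median log2 ratio 0.57, percentile 87.5), progenitors (median log2 ratio -1.09, percentile 30.5), stroma and endothelium (median log2 ratio 0.30, percentile 75.7) and erythroid cells with megakaryocytes (median log2 ratio -0.81, percentile 2.96) did not stand apart. Of 9 stroma and endothelium markers 4 fell (Col1a1, Col1a2, Col3a1 and Sparc) and 3 rose (Kdr, Vwf and Lum), with Kdr from 0.194 to 104.5 CPM. The mean of members was -0.46 for this list and -0.29 for plasmacytoid dendritic cells, on the other side of 0 from their medians. Only 4 B cell, 3 T and NK cell and 2 sex chromosome genes were expressed, too few for a percentile.

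Other function lists lay within the range of random lists: immediate early genes (median log2 ratio 0.82, percentile 96.2), inflammasome and cytosolic sensors (median log2 ratio 0.75, percentile 97.0), migration receptors (median log2 ratio 0.73, percentile 88.7), the unfolded protein response (median log2 ratio 0.71, percentile 78.8), pattern recognition and uptake (median log2 ratio 0.67, percentile 86.4), cholesterol synthesis (median log2 ratio -0.18, percentile 5.42) and reference housekeeping genes (median log2 ratio 0.38, percentile 19.8). The inflammasome list stood apart as higher in 5 of 11 alternative settings, with a median of 2.08 with TPM, and the immediate early list in 1, with 1.53 with TPM. Within them, Fosl1 was at 0 counts untreated and at 14.3 CPM with YB328, and Egr1 fell 13.6-fold. Mlkl had 1 count untreated and 80.8 CPM with YB328. Among the lists, 18 of 35 stood apart, 13 higher and 5 lower, where 1.75 would if the members of a list varied independently. Random lists were drawn gene by gene and members of 1 list can vary together, so 1.75 is not an expectation for these lists. The median log2 ratio of all 10699 genes was 0.17, and it moved to 0.61 with the deposited TPM (length-corrected levels), 0.31 with a minimum of 20 CPM and 0.05 with nuclear protein-coding genes alone. Of all genes that passed, 57.5% were higher with YB328, against 75.0% with TPM.

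The comparison of P. vulgatus with untreated cells asks the same of this bacterium, and the same groups moved. Most cytokine, chemokine, interferon response and glycolysis genes of the lists rose in the P. vulgatus library, and most cell cycle, neutrophil and ribosomal protein genes fell. Cxcl1 (ENSMUSG00000029380.11, chromosome 5, 90891241 to 90893115), a neutrophil-attracting chemokine, rose from 3 counts to 18972, a ratio of 3710.2 (95% interval 1269 to 17993). Saa3 (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700) rose 346-fold (95% interval 319 to 376) to 12834 CPM. Il10 (ENSMUSG00000016529.5, chromosome 1, 131019845 to 131024974), an anti-inflammatory cytokine gene, had 0 counts untreated and 174 CPM with P. vulgatus, at least 897-fold higher. Ccr2 (ENSMUSG00000049103.14, chromosome 9, 124101950 to 124113557), a chemokine receptor gene of monocytes, fell from 141 to 0.304 CPM. In all, 2696 genes rose and 2015 fell among 10699, and 1054 and 785 of these did so by at least 2 on the log2 scale.

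Among cytokine genes 17 of 20 rose and 0 fell (median log2 ratio 2.82, percentile 100). Il6 rose 124-fold (95% interval 101 to 154), Il1a rose from 6.84 to 1185 CPM, Il12b rose 8.14-fold, and Il12a went from 1 count to 130, a ratio of 76.3 (95% interval 13.4 to 3035), again below a minimum of 20 CPM. Csf3, the granulocyte colony-stimulating factor gene, had 1 count untreated and 9413 with P. vulgatus, a ratio of 5522 (95% interval 991 to 218148). Tnf did not pass, at 102 CPM. Among chemokine genes 12 of 18 rose and 2 fell (median log2 ratio 1.96, percentile 99.97), with Cxcl3 up 171-fold and Cxcl10 up 32.7-fold. Ptgs2 rose 895-fold (95% interval 579 to 1465) and Ptges rose 399-fold (95% interval 263 to 636). Nos2 rose to 1144 CPM and Arg1, the arginase gene, rose from 1.68 to 242 CPM, and of 18 immunometabolic enzyme genes 10 rose and 3 fell (median log2 ratio 1.35, percentile 99.7). The regulatory ligand list had 12 of 17 higher and 0 lower (median log2 ratio 3.005, percentile 100), with Cd274 up 8.05-fold, Cd200 up 20.6-fold and Havcr2 up from 0.387 to 28.0 CPM. Hspa1a, a heat shock gene with the near-identical copy Hspa1b, rose from 3.38 to 7820.7 estimated counts, a ratio of 1357 (95% interval from rounded counts 523 to 7418). The noncoding transcript U90926 had 0 counts untreated and 142 CPM with P. vulgatus, at least 735-fold higher, and Plat, the tissue plasminogen activator gene, rose from 3 counts to 3655, a ratio of 715 (95% interval 244 to 3468).

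Of 43 type I interferon response genes 42 rose and 0 fell (median log2 ratio 4.23, percentile 100), with Cmpk2 up 278-fold, Rsad2 up 202-fold, Irf7 up 197-fold and Isg15 up 171-fold. Of 25 interferon gamma response genes 20 rose and 1 fell (median log2 ratio 3.002, percentile 100), and Ifnb1 had 34 counts, at least 6.65-fold higher than untreated, at 1.29 CPM. Of 19 costimulation and maturation genes 14 rose and 1 fell (median log2 ratio 1.75, percentile 99.96). Cd40 rose 9.14-fold, Cd80 rose 2.78-fold, Cd83 rose 3.36-fold, Cd86 rose 5.17-fold and Ccr7 rose 7.51-fold. Of 23 genes of class I presentation 18 rose and 0 fell (median log2 ratio 1.51, percentile 99.5), H2-K1 among them (5.52-fold). The class II list had 1 higher and 3 lower of 13 (median log2 ratio -0.17, percentile 2.66), a median that lay outside random lists on the lower side in 6 of 11 alternative settings. H2-Ab1 was at 2700.0 CPM, and H2-DMa, H2-DMb1 and Ciita, the class II transactivator gene, fell 4.01-fold, 2.31-fold and 2.39-fold.

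Glycolysis and hypoxia genes rose in 27 of 32 cases and fell in 0 (median log2 ratio 2.504, percentile 100). P4ha2, a collagen prolyl hydroxylase gene, rose from 3.10 to 112 CPM, Slc16a3 rose 19.3-fold, and Vegfa, the vascular growth factor gene, rose 13.7-fold. NF-kB targets and feedback genes rose in 22 of 35 cases and fell in 1 (median log2 ratio 1.47, percentile 100), NRF2 genes in 20 of 24 and 0 (median log2 ratio 1.53, percentile 99.8), and lysosomal genes in 20 of 33 and 1 (median log2 ratio 1.31, percentile 99.8). Hmox1 rose 49.0-fold, Tnfaip3 rose 8.52-fold and the cathepsin gene Ctsd rose 5.90-fold. Of 25 Toll-like receptor signalling genes 11 rose and 2 fell (median log2 ratio 0.85, percentile 97.53), a list that stood apart in 9 of 11 alternative settings. Cd14 rose 19.99-fold, Tlr1 rose from 0.323 to 16.5 CPM, Tlr4 rose 3.47-fold and Tlr3 rose 6.02-fold, again without reaching the minimum with TPM or with at least 20 CPM. Tlr2 (164 CPM) and Tlr7 (9.47 CPM) did not pass, with log2 ratios of 0.97 and 0.82, though both did with TPM, at 1.26 and 1.30. Tlr11, named by the rule for YB328 only, fell from 6.71 to 0.0379 CPM, the latter being 1 count. Tlr9 and Tlr5 stood at 0.682 CPM and 0 counts.

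Of 33 cell cycle genes 1 rose and 26 fell (median log2 ratio -2.14, percentile 0), with Top2a down 37.0-fold, Ube2c down 51.4-fold and Aurkb down 58.9-fold. Of 14 neutrophil markers 12 fell (median log2 ratio -1.99, percentile 0), with S100a9 down 26.7-fold, S100a8 down 10.5-fold and Ngp down 10.3-fold, while Lcn2, an inducible granule protein gene, rose 13.8-fold. Ribosomal protein genes fell in 29 of 44 cases and rose in 0 (median log2 ratio -1.10, percentile 0), and all 13 mitochondrially encoded genes fell (median log2 ratio -4.37, percentile 0), again beside the larger ribosomal RNA and mitochondrial share of the untreated library. The oxidative phosphorylation list had median log2 ratio -0.12, percentile 0.160. Its median turned to 0.16 with TPM, while the list stood apart as lower in 11 of 11 alternative settings. Plet1 (ENSMUSG00000032068.14, chromosome 9, 50494525 to 50505482), which encodes a surface protein, fell 181-fold (95% interval 153 to 216). Col1a1 and Col1a2 fell 97.8-fold and 90.4-fold, and Col6a2 fell 86.2-fold. The DNA replication genes Dna2 and Pclaf fell 106-fold and 64.5-fold, and the water channel gene Aqp3 fell 62.7-fold. The transcription factor gene Egr3 and the lectin gene Clec4b1 were at 0 counts with P. vulgatus, at least 196-fold and at least 206-fold lower than untreated, though Egr3 stayed below the minimum with TPM.

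Among marker lists, type 1 dendritic cell genes had 5 higher and 3 lower of 11 (median log2 ratio 0.55, percentile 66.7), with Irf8 up 5.10-fold, Batf3 at 97.2 CPM, Xcr1 at 3.33, Itgae at 1.17 and Clec9a at 0 counts. Type 2 markers had 3 higher and 6 lower of 12 (median log2 ratio -0.50, percentile 3.65). Macrophage markers had 7 higher and 1 lower of 16 (median log2 ratio -0.14, percentile 5.82), though the mean of members turned to 0.80. Monocyte markers had 6 higher and 4 lower of 14 (median log2 ratio 0.71, percentile 88.5). Lists that did not stand apart were those for plasmacytoid cells (median log2 ratio 0.60, percentile 84.0), mast cells with basophils and eosinophils (median log2 ratio 0.93, percentile 96.2), progenitors (median log2 ratio -1.19, percentile 26.4), stroma and endothelium (median log2 ratio 0.05, percentile 59.6), erythroid cells (median log2 ratio -0.64, percentile 7.94), immediate early genes (median log2 ratio 0.81, percentile 96.5), inflammasome and sensors (median log2 ratio 0.50, percentile 86.9), migration receptors (median log2 ratio 0.70, percentile 88.2), the unfolded protein response (median log2 ratio 0.57, percentile 66.9), pattern recognition (median log2 ratio -0.02, percentile 13.2), cholesterol synthesis (median log2 ratio 0.08, percentile 31.8) and housekeeping genes (median log2 ratio 0.54, percentile 46.8). Of 11 alternative settings, the inflammasome list stood apart as higher in 3 (median up to 1.90 with TPM), the immediate early and mast cell lists as higher in 2 each and the type 2 dendritic cell list as lower in 2. The stroma median turned to -2.41 and stood apart with a minimum of 20 CPM. Here too 18 of 35 lists stood apart, 13 higher and 5 lower. The median of all genes was 0.15, and it moved to 0.49 with TPM, 0.27 with a minimum of 20 CPM and 0.02 with nuclear protein-coding genes alone. Of all genes that passed, 57.2% were higher with P. vulgatus, against 70.3% with TPM.

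**Figure D2:**
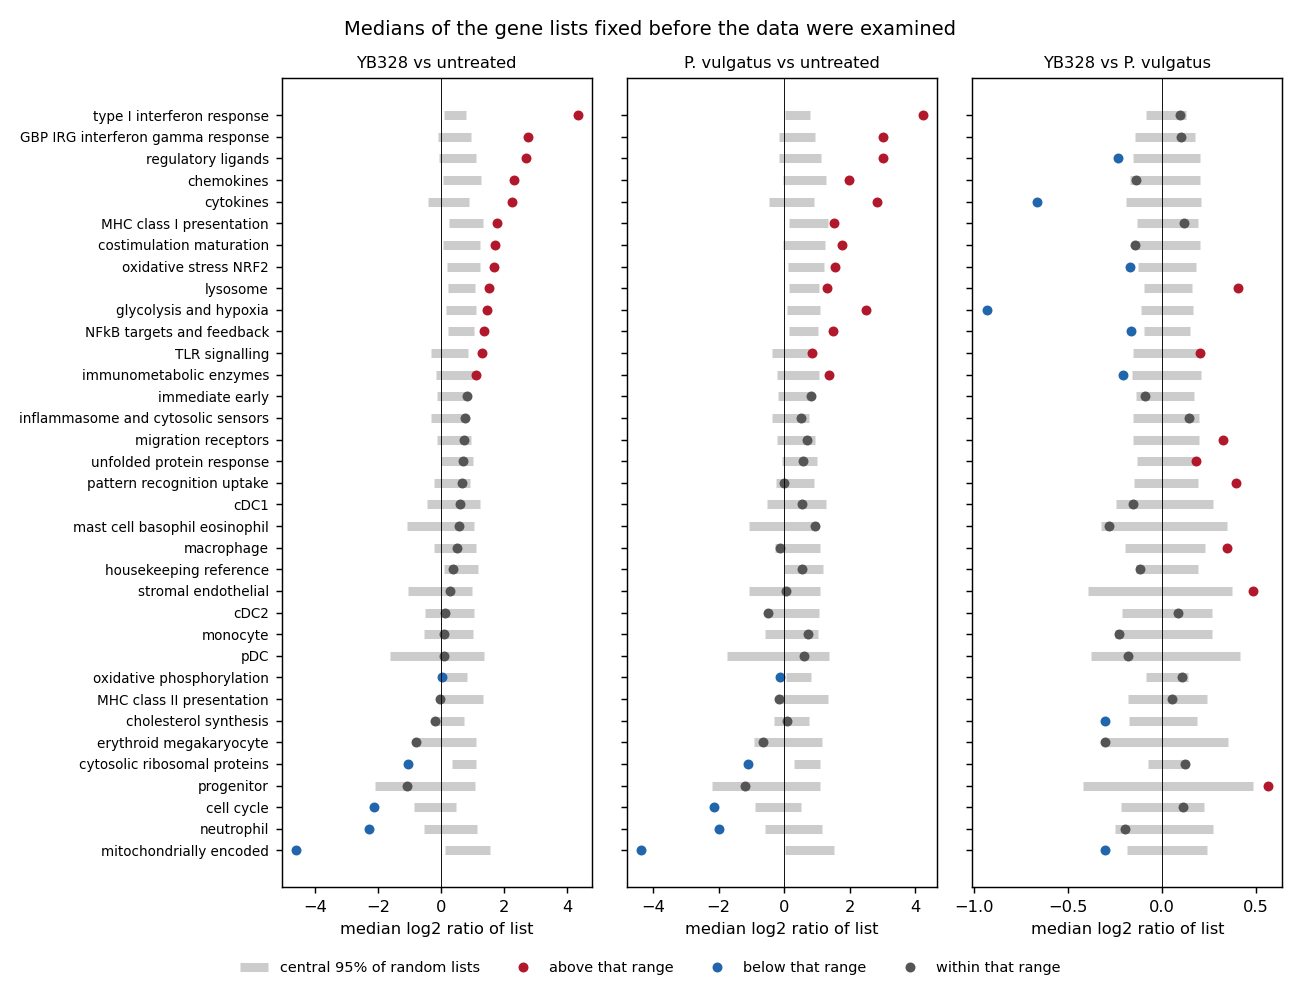
Median log2 ratio (x axis; the panel on the right has its own scale) of each of 35 gene lists in the 3 comparisons, 1 library per group; grey bars hold the central 95% of matched random lists, red points lie above and blue points below it. Type I interferon genes lie at 4.34 with YB328 and 4.23 with P. vulgatus against untreated, and glycolysis and hypoxia genes at -0.94 between the bacterial libraries.

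The genes that passed against the shared untreated library overlapped widely between the bacteria. Of the genes that rose with YB328 and with P. vulgatus, 2265 were shared, where independent lists would share 667, and of those that fell 1620 were shared, where independent lists would share 368. Nos2, Cxcl1, Ptgs2, Ptges, Cmpk2 and Rsad2 were among the highest of both comparisons, and Col1a1, Col1a2, Col6a2 and Clec4b1 among the lowest. Only 5 genes passed in opposite directions. Across the 10699 genes the log2 ratios had Pearson r 0.94 and Spearman rho 0.94, with genes not being independent replicates. Both ratios share the untreated library, so unchanged groups were simulated against it. Counting noise alone gave 0 shared genes in either direction, with r 0.64 and covariance 0.0074. With a spread between libraries of 0.2 (coefficient of variation) the simulations shared 18.1 higher and 6.10 lower genes, with r 0.51, and with a spread of 0.4 they shared 472 and 333, with r 0.51. The covariance was 2.32, against 0.0897 and 0.354 in these simulations, a difference of 2.23 and 1.97. The simulations gave each gene independent noise. They left out shifts of whole gene classes in the untreated library, such as its ribosomal and mitochondrial share, which enter both ratios. The untreated library cannot be divided, so how much of the excess comes from sharing it cannot be told.

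**Figure D3:**
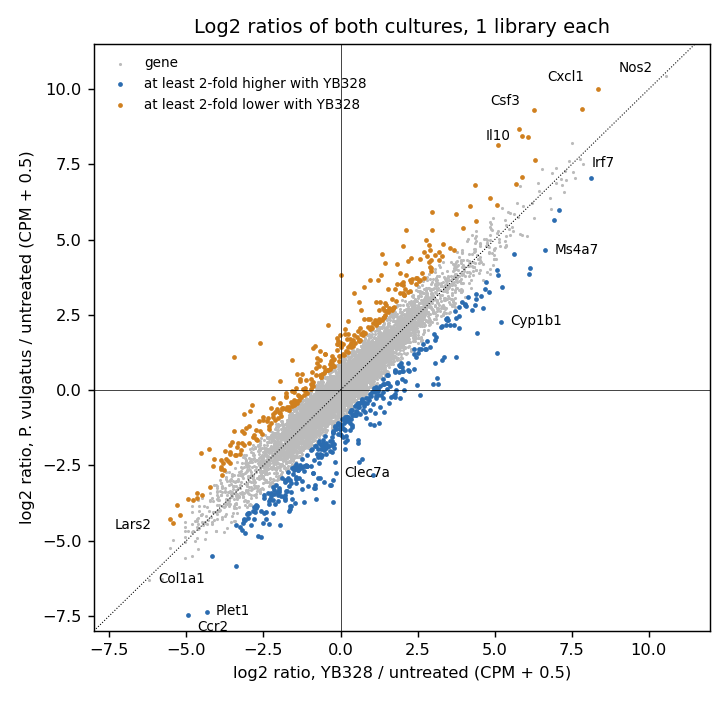
Log2 ratio of each of 10699 genes for YB328 over untreated (x axis) and P. vulgatus over untreated (y axis), with 0.5 CPM added and 1 library per group; the dotted line marks equal ratios, and coloured points passed between the bacterial libraries. The points follow the line (r 0.94), with 364 genes higher and 309 lower with YB328.

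The comparison of YB328 with P. vulgatus, whose ratios leave out the untreated library, asks what sets the strains apart. The untreated library still took part in the scaling, and a gene could meet the minimum CPM in it alone. The medians of the lysosomal, pattern recognition and macrophage lists lay above those of random lists, and the medians of the glycolysis and hypoxia list and the cytokine list lay below, with most members of each list not passing. Lists share members and so are not separate results. Gpnmb and Cd68 are in the lysosomal and macrophage lists, Mertk in the macrophage and pattern recognition lists, and Il10 in the cytokine and regulatory ligand lists. Cyp1b1 (ENSMUSG00000024087.4, chromosome 17, 79701537 to 79715061), a cytochrome P450 gene, was 7.96-fold (95% interval 7.14 to 8.91) higher with YB328, and Ahrr (ENSMUSG00000021575.16, chromosome 13, 74211118 to 74292331), the aryl hydrocarbon receptor repressor gene, was 9.09-fold (95% interval 7.29 to 11.45) higher. Clec7a (ENSMUSG00000079293.11, chromosome 6, 129461591 to 129472779), which encodes the beta-glucan receptor dectin, stood at 381 CPM untreated, 55.7 with P. vulgatus and 342 with YB328. Il10 was 5.95-fold (95% interval 5.51 to 6.42) lower with YB328 than with P. vulgatus. In all, 364 genes were higher and 309 lower with YB328, 6.29% of 10699, and 57 and 39 of these by at least 2 on the log2 scale. They include genes below 5 CPM in both bacterial libraries that reached the minimum only untreated. Ccr2, for example, stood at 141 CPM untreated, 0.304 with P. vulgatus and 4.11 with YB328. Of the 364, 201 had fallen and 57 had risen with P. vulgatus against untreated, while 106 had fallen and 122 had risen with YB328. Of the 309, 55 had fallen and 169 had risen with P. vulgatus, while 112 had fallen and 102 had risen with YB328. Each of these counts shares a library with the ratio that picked the genes, so they lean to 1 side by the picking alone.

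Of 32 glycolysis and hypoxia genes 11 fell and 0 rose (median log2 ratio -0.94, percentile 0). The hormone gene Adm fell from 16.4 CPM with P. vulgatus to 2.09 with YB328, P4ha2 fell from 112 to 24.3, and the glucose transporter gene Slc2a3 fell from 23.4 to 8.15. Of 20 cytokine genes 7 fell and 0 rose (median log2 ratio -0.67, percentile 0). Csf3 was 8.27-fold (95% interval 7.79 to 8.80) lower, Il19 8.83-fold (95% interval 7.10 to 11.1) lower and Il6 2.20-fold lower with YB328. Il12a and Il12b did not pass, at 4.92 and 7.96 CPM and at 122 and 98.0 CPM, and neither did Tnf. Saa1 was 10.9-fold (95% interval 8.47 to 14.1) lower, Arg1 5.52-fold lower, U90926 8.43-fold lower and the heat shock copies Hspa1a and Hspa1b 7.56-fold and 6.92-fold lower. The connexin gene Gja1 was 7.85-fold lower and the eosinophil granule gene Prg2 6.06-fold lower. NF-kB targets (median log2 ratio -0.17, percentile 0.130, with Saa3 5.05-fold lower), regulatory ligands (median log2 ratio -0.24, percentile 0.320), NRF2 genes (median log2 ratio -0.17, percentile 0.6), immunometabolic enzymes (median log2 ratio -0.21, percentile 0.690) and cholesterol synthesis genes (median log2 ratio -0.31, percentile 0.0200) lay below the range of random lists. Most members of these lists did not pass. Of 35 NF-kB targets 3 fell and 0 rose, of 17 regulatory ligands 2 and 0, and of 18 immunometabolic genes 4 and 2, Ptgs1 among the risen (4.09-fold). The only NRF2 gene that passed, Nqo1, was 2.64-fold higher, and the only cholesterol gene that passed, Tm7sf2, was 2.70-fold higher, both against the side of their list. The calls of the regulatory ligand, NRF2 and immunometabolic lists held in 10 of 11 alternative settings each.

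Of 33 lysosomal genes 6 rose and 0 fell (median log2 ratio 0.41, percentile 100). Gpnmb was 2.89-fold (95% interval 2.86 to 2.91) higher with YB328, Cd68 2.24-fold higher and Tfeb, a regulator of lysosomal genes, 3.08-fold higher. Of 27 pattern recognition and uptake genes 7 rose and 2 fell (median log2 ratio 0.39, percentile 99.97), among them Itgax, which encodes CD11c and was 3.35-fold higher, and Clec10a, 4.29-fold higher. Clec10a fell with both bacteria, from 49.3 CPM untreated to 2.04 with P. vulgatus and 8.77 with YB328. Of 16 macrophage markers 5 rose and 1 fell (median log2 ratio 0.35, percentile 99.8), with Ms4a7 4.04-fold higher. Migration receptors (median log2 ratio 0.33, percentile 99.95) had 2 higher and 1 lower of 23, with Ccr2 at 0.304 CPM with P. vulgatus and 4.11 with YB328. Toll-like receptor signalling (median log2 ratio 0.20, percentile 97.8) had 3 higher and 2 lower of 25, and stood apart in 9 of 11 alternative settings. Tlr12, Tlr13 and Tlr7 were 10.1-fold, 2.27-fold and 2.23-fold (95% interval 1.92 to 2.60) higher, the last with a log2 ratio of 1.12 that was 0.998 and no longer passed after thinning to equal depth. The 2 lower genes were Cd14 and Ticam2, with log2 ratios of -1.11 and -1.12. Tlr9 did not pass, at 0.682 and 1.80 CPM. The unfolded protein response list (median log2 ratio 0.18, its percentile on the upper limit) stood apart in 3 of 11 alternative settings, stroma and endothelium (median log2 ratio 0.49, percentile 99.3) in 10 of 11, and progenitors (median log2 ratio 0.57, percentile 98.9) in 5 of 10. Of 9 stroma and endothelium genes 2 rose and 1 fell. The risen were Col3a1, at 17.1 CPM untreated, 0.871 with P. vulgatus and 3.01 with YB328, and Sparc, at 41.5, 0.947 and 6.02. The 11 progenitor genes had 3 higher and 3 lower, and their median turned to -0.27 with no minimum CPM. Plet1, Jaml and Tmem154 were 8.85-fold, 7.37-fold and 6.92-fold higher, and in each the untreated library was highest, at 946, 129.7 and 93.8 CPM. Gja5, Slc39a2, Egr2, Ccn3, Dcstamp and Angptl2 were also among the most elevated, from 9.25-fold for Gja5 to 5.005-fold for Angptl2.

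**Figure D4:**
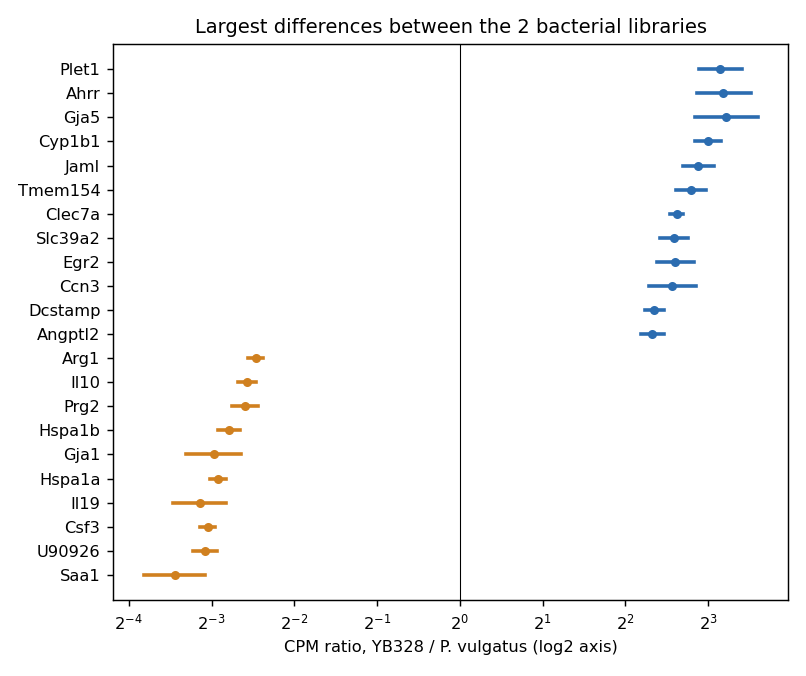
Ratio of CPM, YB328 over P. vulgatus (x axis, log2 scale), for the 12 highest and 10 lowest named genes of this comparison (1 library each); lines are 95% intervals that cover counting error only. Plet1 lies at 8.85-fold higher with YB328, and Saa1 at 10.9-fold lower.

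The maturation genes differed little between the bacterial libraries. Of 19 costimulation genes 0 rose and 0 fell (median log2 ratio -0.15, percentile 2.71, apart as lower in 3 of 11 alternative settings), and Cd40, Cd80, Cd83, Cd86, Ccr7 and Cd274 had log2 ratios of -0.24, -0.42, -0.06, 0.19, -0.11 and -0.24. Type I interferon genes (median log2 ratio 0.10, percentile 92.3) had 2 higher, Ifit2 (2.16-fold) and Ly6a (2.13-fold), and 1 lower, Mx2 (3.44-fold), of 43. Interferon gamma response genes (median log2 ratio 0.10, percentile 86.6), class I (median log2 ratio 0.12, percentile 87.5) and class II presentation (median log2 ratio 0.05, percentile 59.4) had no member that passed. Chemokines (median log2 ratio -0.14, percentile 5.12) had 2 higher, Ccl24 (8.03-fold) among them, and 4 lower, including Cxcl1 (3.21-fold) and Cxcl2 (2.68-fold). H2-K1, H2-Ab1, Irf8, Batf3, Tlr2, Tlr3, Tlr4 and Cxcl10 did not pass, with log2 ratios of 0.06, -0.31, 0.21, 0.30, 0.20, -0.18, 0.36 and -0.15. Xcr1, Itgae, Ifnb1, Cxcl9 and Tlr5 were below 5 CPM in all 3 libraries, and so could not pass.

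Mitochondrially encoded genes lay below random lists (median log2 ratio -0.31, percentile 0.110) with no member passing, beside mitochondrial protein-coding shares of 0.748% and 0.577%. Within the range of random lists were neutrophil markers (median log2 ratio -0.20, percentile 5.66), cell cycle (median log2 ratio 0.11, percentile 83.9), ribosomal proteins (median log2 ratio 0.12, percentile 95.1), oxidative phosphorylation (median log2 ratio 0.10, percentile 91.4), immediate early genes (median log2 ratio -0.09, percentile 7.79), inflammasome and sensors (median log2 ratio 0.14, percentile 93.0), housekeeping genes (median log2 ratio -0.12, percentile 4.72), type 1 (median log2 ratio -0.16, percentile 9.16) and type 2 dendritic cell markers (median log2 ratio 0.09, percentile 70.2), plasmacytoid cells (median log2 ratio -0.18, percentile 14.5), monocytes (median log2 ratio -0.23, percentile 3.46), mast cells with basophils and eosinophils (median log2 ratio -0.28, percentile 4.33) and erythroid cells (median log2 ratio -0.31, percentile 2.86). Several of these calls turned with the setting. Of 11 alternatives the neutrophil list stood apart as lower in 4 and the inflammasome list as higher in 2, and the erythroid list as lower in 4 of 10. The mast cell list stood apart as higher with TPM (median 0.58) and as lower with a minimum of 20 CPM (median -0.66). Of 35 lists 16 stood apart, 8 higher and 8 lower. In simulations of unchanged genes that compared these libraries, 171 of 10499 genes passed at a spread of 0.2 between libraries and 2216 at 0.4, so the 673 genes observed lie between the counts that such spreads alone would give.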

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

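The tests of shared copies, of neutrophil-lineage cells and of list percentiles over all settings were chosen only after the result was seen. The other tests had their limits written before their own values were computed, although every pattern, including the glycolysis and hypoxia median, was picked from main results already seen.

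Because they passed in opposite directions with YB328 and with P. vulgatus against untreated cells, 4 genes drew attention, and these differences between groups were not tested. Lower with YB328 was Gm50241, with a difference of log2 ratios of -4.57, at 5.02 CPM untreated, 11.4 with P. vulgatus and 0 with YB328. Higher with YB328 were Gm10273, with a difference of 3.89 at 3.05, 0 and 6.93 CPM in the same order, Dph1, with 2.33 at 2.88, 1.09 and 7.48 CPM, and Irgc1, with 2.24 at 4.45, 1.70 and 9.91 CPM. Gm50241, Gm10273 and Dph1 had estimated counts that were not whole, for Gm50241 77.74 untreated, 300.28 with P. vulgatus and 0 with YB328. Gm10273 is annotated as a processed pseudogene. A shift of reads between gene models, as described for Nnt below, was not tested for these genes. All 4 were named after their values were seen.

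The untreated library held more ribosomal RNA, mitochondrial RNA and Malat1 than either bacterial library. Reads shared between near-identical copies would leave the summed share of the family, nuclear copies and Lars2 included, nearly level, but the smaller ratio of untreated to treated was 14.5, which excludes that as the only cause. Loss of long transcripts would make the log2 ratio rise with gene length, and the smaller Spearman rho was -0.0877, which excludes it in this form. A larger share of nuclear RNA could lower other nuclear-retained noncoding RNAs, whose medians were -1.25 with YB328 and -0.82 with P. vulgatus, and this cannot be told apart from other causes because 7 expressed genes gave a value between the limits set for the test. Whether the makeup reflects the RNA sample or the response of the cells stays open without a repeat of the untreated library.

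The medians of the neutrophil, cell cycle and ribosomal protein lists were lower in both bacterial libraries. A larger ribosomal and mitochondrial share of the untreated library would lower its other genes alike, raise the ratios and keep these lists level with matched random lists, but their percentiles were at most 0.29 in every setting, which excludes it as the only cause. On nuclear protein-coding genes alone the highest of the 6 medians was -1.20, a test that decides nothing by itself because that setting also lowered the median of all genes. Gene length and GC content are excluded as the only cause, with a highest median of -1.72 after removing a trend on length, GC content and mean expression, and -1.26 without expression, a fit added after the result was seen. Fewer cells of the neutrophil lineage in the bacterial cultures may account for the neutrophil markers, of which 1 of 14, Lcn2, lay above 0 in both comparisons, but cannot be told apart from lower expression per cell because bulk RNA holds no count of cells.

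Glycolysis and hypoxia genes were lower with YB328 than with P. vulgatus. Over 5 other scalings the highest median was -0.81, which excludes scaling, and after removing a trend on length, GC content and mean expression it was -0.97, as without expression, which excludes that trend. Less hypoxia-type signalling with YB328 was tested on 21 expressed hypoxia-induced genes outside the list. Their median log2 ratio was -0.76, at percentile 0 of matched random lists, with 6 lower and 0 higher, a result consistent with this explanation. Whether oxygen, cell density or bacterial products might differ between the cultures was not tested, and 1 library per group leaves differences between cultures open.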

How the results depend on the processing

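No paired analysis was possible because each group has 1 library and the labels give no pairing. Of 145 single-gene results, each a named gene in a comparison, 122 kept their side of the rule of size under all 10 alternatives for genes and 23 did not. Direction was checked only for genes that passed. Taken setting by setting, 1425 values stayed the same, 11 became stronger and 14 weaker. For genes these words mean that a call was gained or lost, not that the ratio grew or shrank. Of list results, 1074 stayed the same, 46 became stronger, 21 weaker and 5 reversed. Reversals were changes of sign of the median, and the other results were judged by whether the list stood apart. A list could reverse in this sense and still stand apart on the same side. A reversal was counted only for lists that stood apart. Lists that did not could change sign and still count as the same. Macrophage markers for P. vulgatus with untreated did so, with values from -0.29 to 0.80, and pattern recognition ran from -0.29 to 0.67 there. Of counts 108 stayed within 1.5 times and 15 moved. With no minimum CPM more genes were considered, and the genes lower were 3570 (YB328 with untreated), 3647 (P. vulgatus with untreated) and 2934 (shared), while YB328 with P. vulgatus gave 780 higher and 767 lower. A minimum of 20 CPM considered fewer genes and gave 977, 1046 and 814 lower, and 149 higher and 126 lower between the bacterial libraries. With 2 CPM added, which shrinks ratios of weak genes, 230 were higher and 189 lower between them. With the deposited TPM, 1155, 1336 and 1002 genes were lower, and the cause was not tested. The oxidative phosphorylation median reversed to 0.16 with TPM for P. vulgatus, and for YB328 to -0.10 on nuclear protein-coding genes, an alternative chosen after seeing the data, and to -0.0241 with the mean of members. The list still stood apart as lower in 11 of 11 alternatives for P. vulgatus and in 10 of 11 for YB328. The progenitor median between the bacterial libraries reversed to -0.27 with no minimum and -0.11 with the mean of members. For these list medians the cause was not tested. List calls that changed in a single alternative besides those given elsewhere were class II presentation in the other 2 comparisons, cell cycle, chemokines and monocytes between the bacterial libraries, type 2 dendritic cells, macrophages, erythroid cells and oxidative phosphorylation for YB328, and lysosome and pattern recognition for P. vulgatus. U90926, Tsix, Lars2 and Clec7a, annotated as other than protein-coding or left out by name, have no call on nuclear protein-coding genes. Depth limits weak genes most: 3 counts correspond to 0.194 CPM in the untreated library, the shallowest.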

Other observations

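The tests in this part had their limits written before their values were computed, but Ahrr, Cyp1b1, Hspa1a and Hspa1b were seen first. Ahrr and Cyp1b1 are targets of the aryl hydrocarbon receptor, and higher receptor activity with YB328 might raise its other targets. The 7 expressed other targets had a median log2 ratio of 0.25 between the bacterial libraries, at percentile 92.3, which lies between the limits set for the test and leaves the explanation open. Hspa1a and Hspa1b were lower with YB328, and 11 other expressed heat shock genes had a median of -0.16, at percentile 5.59, which also may or may not reflect a wider heat shock difference.

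Nnt, a mitochondrial enzyme gene, is listed as 2 overlapping models on chromosome 13, and the counts moved from 1 model to the other between libraries. Summed over both it stood at 10.5, 8.41 and 13.3 CPM in the untreated, P. vulgatus and YB328 libraries. The gene was chosen after its values were seen. Genes on the Y chromosome from the fixed list had at most 7 counts in a library, and Xist stood at 293, 45.4 and 35.5 CPM in the untreated, P. vulgatus and YB328 libraries.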
